A study of Homo sapiens with 6 samples.

How the data were processed

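RNA from 6 cultures of H1299 cells was measured on Affymetrix arrays, 3 after infection with an empty retroviral vector and 3 after infection with a vector that, per the labels, expresses CHES1. CHES1 is the older name of FOXN3, a forkhead transcription factor. Per the labels' protocols, total RNA was extracted with Trizol and made into biotin-labelled cRNA with a whole-transcript expression kit. The deposited values are log2 expression values, 1 per probe set and array, made with Affymetrix Expression Console and RMA per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set. Versions of these tools, the name of the array design, its genome build and the parts of each transcript that the probes cover are not given in the sources used here. Scan dates and hybridization batches are also not given in the sources used here, so no batch could be entered in a fit.

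The table held 53617 probe sets for each of the 6 arrays. The platform annotation used here gave 16098 probe sets 1 gene symbol, gave several to 0 and left 37519 unnamed here. All 16098 were matched by gene ID to RefSeq gene records of the GRCh38.p14 assembly. These served to update symbols, also those of the gene lists, and to give the type of each gene. Each gene was represented by its probe set with the highest mean over the 6 arrays, which left 14884 genes, of which 11916 are protein-coding and 1072 are microRNA genes. Of these genes, 779 had several probe sets. Among the called genes, 13 had several, and 0 of those had a probe set that moved the other way. A total of 403 named probe sets held values identical to those of another probe set on every array, and 1 called gene, MAPK8IP1P2, was among them. No filter on dim probe sets was applied.

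The comparison was fitted in R 4.3.3 with limma 3.58.1, using lmFit and eBayes on the log2 values with group as the only term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 14884 genes. Differences are given as log2 values of the arrays labelled CHES1 minus the empty vector arrays, with the moderated standard error (SE), and group values as mean ± SD. The exact permutation tests were two-sided. With 3 arrays against 3 the smallest p they can give is 0.1, so they cannot pass 0.05. The labels describe the replicates as independent, and the number of arrays limits the precision. The replicate numbers 1 to 3 occur in both groups, and nothing in the labels says that a number marks a shared day or culture, so they were not used as pairs.

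The design, 33 gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Listed genes without a named probe set were not measured, so a list that was not called speaks only for its measured members. Camera was also run with the correlation estimated per list and in its rank-based form, and fry was run as a test of each list by itself. Named genes are FOXN3, the measured PIM and DYRK kinases, the 12 called genes with the largest decrease and the 12 with the largest increase whose arrays did not overlap between groups, and up to 2 called genes per direction from each list. Uncharacterised, microRNA and long non-coding symbols were passed over in the ranking by size, which left out 2 genes that rose and left 10 of the 12 places for increases filled. Genes named outside this rule are said to have been chosen after their values were seen. The named genes numbered 43.

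The scripts were tested on simulated data for this comparison with 14884 genes, 200 changed genes in each of 5 runs and the spread of the real arrays. The fit recovered 42.4% of genes changed by 0.4 on the log2 scale, 84.4% at 0.8, 96.4% at 1.2 and 99.2% at 1.6, and 4.62% of its calls were false. A list shifted by -0.3 was called in 5 of 5 runs, and 0 of 155 tests of other lists were called. The simulated noise was independent between genes, so these rates do not cover lists whose genes vary together, where the preset correlation may call too many. Alternatives covered the replicate number as a block, the empirical Bayes prior, array quality weights, filters on dim probe sets, 3 further normalizations, the summary of several probe sets, the features tested, the thresholds, the set test, and leaving out each array, and those added later are named with their results. Figures were drawn with matplotlib 3.10.9.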

Results

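The series measured gene expression in H1299, a human non-small cell lung carcinoma line that lacks p53, after infection with a retroviral vector for CHES1 (FOXN3). Per the labels, cells received the empty vector or the one for CHES1, were selected for 3 days with 5 µg/ml puromycin, and were collected on day 5 after infection. Each group had 3 arrays. The median log2 value per array lay between 5.957 and 6.002, and single probe sets ranged from 1.19 to 14.06. Over the 14884 genes, which are not independent replicates, arrays of the same group correlated at 0.994 to 0.996 and arrays of different groups at 0.993 to 0.995. The free-text descriptions of CHES1 replicates 2 and 3 name CHES2 and CHES3, while their titles and other labels name CHES1.

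FOXN3, the gene introduced by the vector, was not higher in the arrays labelled CHES1. Its log2 expression was 8.53, 8.13 and 8.20 in the empty vector arrays and 8.12, 8.20 and 8.15 in the arrays labelled CHES1, or 8.29 ± 0.217 against 8.16 ± 0.0385 (SD, n = 3 each; exact permutation p = 0.5). The difference was -0.13 (SE 0.107, 95% confidence interval -0.38 to 0.12, limma adjusted p = 0.701), so an increase above 1.09-fold lay outside the interval. Without empty vector replicate 1 the difference was -0.0047. Whether probe set 16795664, which measured FOXN3, lies in the part of the transcript that the vector carries is not given in the sources used here. The labels were not checked by the introduced gene, and the group is therefore called the arrays labelled CHES1, with CHES1 replicates 1 to 3 as the names of its arrays. Expression from the vector is not shown by these values. FOXN2, the closest relative of FOXN3 on the list of FOXN and FOXR genes, fell by 0.58 (SE 0.0678, limma adjusted p = 0.00739), from 9.80 ± 0.069 to 9.22 ± 0.0711 (SD, n = 3 each). It was the called member among 6 measured, with 1 lower adjusted over the list alone, and the list as a whole was not called (median -0.0078, camera adjusted p = 0.804).

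**Figure D1:**
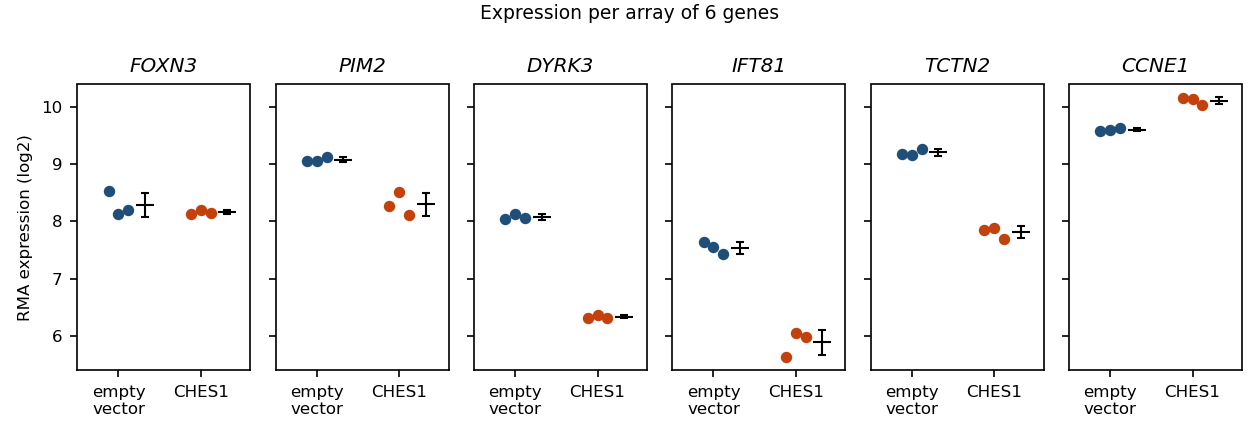
Log2 RMA expression of 6 genes on each array (points), for 3 empty vector arrays (blue) and 3 arrays labelled CHES1 (orange), with the group mean and SD beside the points. FOXN3 overlapped between the groups, whereas DYRK3 lay at 8.08 ± 0.0494 against 6.34 ± 0.0299, and PIM2, IFT81 and TCTN2 also lay lower and CCNE1 higher in all 3 arrays labelled CHES1.

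The question of the design was which genes differ between cells infected with the vector for CHES1 and cells infected with the empty vector. The changes were mostly decreases. The largest included DYRK3, a kinase gene, and genes tied to cilia and flagella. Among the few genes that rose were KRTAP9-1, from a low level, cyclin E1 (CCNE1) and carbonic anhydrase 2 (CA2). limma called 236 of 14884 genes, 12 higher and 224 lower, so that 94.9% of the called genes were lower. At least a 1.5-fold change was reached by 2 higher and 108 lower genes, and at least a 2-fold change by 0 higher and 27 lower genes. In all 236 called genes the 3 arrays of one group lay on one side of the 3 of the other, as did 18.6% of all genes, where chance gives 10%. At an unadjusted p under 0.05 there were 634 higher and 1129 lower genes, 1763 together, against 744.2 by chance. The count depended on the number of arrays and on which array was left out. It was 103, 107 and 124 without empty vector replicates 1, 2 and 3, and 96, 160 and 147 without CHES1 replicates 1, 2 and 3. Other settings called more, with 36 of 348 genes higher under array quality weights, 26 of 372 under the trend and robust prior, 23 of 304 and 36 of 385 at a mean log2 of at least 5 and 6, and 23 of 302 among protein-coding genes only, a setting chosen after the data were seen, while 44 of all probe sets were called, 0 of them higher (2058 higher at an unadjusted p under 0.05).

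**Figure D2:**
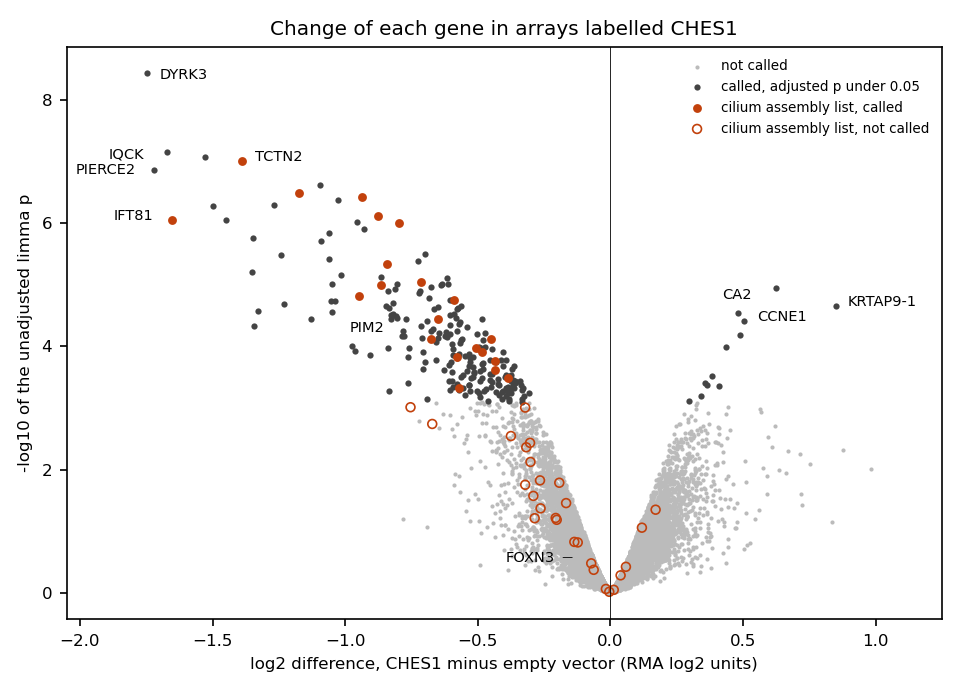
Each point is 1 of 14884 genes, with the log2 difference (arrays labelled CHES1 minus empty vector, n = 3 each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Of 236 called genes, 224 lie to the left of 0 and 12 to the right, and 21 of the 48 measured cilium assembly genes (orange) are called, all lower.

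The gene with the largest decrease was DYRK3 (probe set 16676633), which encodes a dual-specificity kinase. It fell by 1.75 (SE 0.0588, limma adjusted p = 5.54e-05), a level 3.35-fold lower in the arrays labelled CHES1. Next came PIERCE2, a protein of the inner wall of ciliary microtubules, which fell by 1.72 (SE 0.0935, limma adjusted p = 0.000406), from 8.37 ± 0.0645 to 6.65 ± 0.171. IQCK, which carries a calmodulin-binding motif, fell by 1.67, and IFT81, a tubulin-binding subunit of the intraflagellar transport B complex, fell by 1.65 (SE 0.116, limma adjusted p = 0.000938). MATCAP2, a microtubule-associated carboxypeptidase, fell by 1.53, the cilium-associated protein gene CABCOCO1 fell by 1.498, and WDR54 fell by 1.45. TCTN2, a component of the ciliary transition zone, fell by 1.39 (SE 0.0722, limma adjusted p = 0.000364). SAMD15 fell by 1.35, and DYNC2I2, an intermediate chain of the dynein that runs within cilia, fell by 1.35 from a high level of 10.48 ± 0.0202 to 9.13 ± 0.21. CFAP36, named for cilia and flagella, fell by 1.34, and ROPN1L, a protein of sperm flagella, fell by 1.33. The limma adjusted p of these 12 genes was at most 0.00863.

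PIM2, a growth-promoting serine/threonine kinase that the study is known to have named as lowered by CHES1, was lower in the arrays labelled CHES1. It fell by 0.78 (SE 0.0998, limma adjusted p = 0.0106), from 9.08 ± 0.0394 to 8.30 ± 0.197 (SD, n = 3 each), or 1.72-fold, and its 3 arrays did not overlap with the controls (exact permutation p = 0.1, the smallest possible). Of the 8 PIM and DYRK kinases, DYRK3, PIM2 and DYRK1B were called. DYRK1B fell by 0.66 (SE 0.0872, limma adjusted p = 0.0123). The other members did not pass, with differences of -0.24 for DYRK1A, -0.12 for DYRK2, -0.07 for DYRK4, -0.01 for PIM1 and 0.10 for PIM3, and the sign of PIM1 turned positive under 2 of the 3 other normalizations (0.020 with repeated quantile normalization and 0.011 with cyclic loess). Adjusted over the list alone, 4 members were lower. PIM2 and DYRK3 were chosen by the study on these samples, so that neither this count nor the list's direction is independent evidence. The list was called lower by camera (median -0.18, adjusted p = 5.39e-05) and by fry (adjusted p = 0.00804), but had an adjusted p = 0.481 with an estimated correlation and was not called by rank-based camera (adjusted p = 0.0758). The call of PIM2 was lost at a limma adjusted p of 0.0525, 0.0527 and 0.0557 without empty vector replicate 1, empty vector replicate 3 and CHES1 replicate 1, where the range over all alternatives was 0.000975 to 0.0557. DYRK1B was also lost without some arrays, with a highest adjusted p of 0.0633, while that of DYRK3 was 0.00274. DYRK1A, not called in the main fit, was called lower under 1 alternative (limma adjusted p = 0.0348).

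Genes of the cilium assembly list, which covers the primary and the motile cilium, fell as a group. The values are RNA levels, and cilia themselves were not measured. Of 61 listed cilium assembly genes, 48 were measured, and 21 of these (43.8%) were called lower and 0 higher, where 1 was higher at an unadjusted p under 0.05. Among the 14836 genes outside the list, 203 (1.37%) were called lower (odds ratio 56.0, two-sided Fisher's exact test p = 3.23e-26, with genes taken as independent). Adjusted over the list alone, 32 were lower and 0 higher. The median difference of the 48 genes was -0.35, and 43 lay below 0. The list was called by camera (adjusted p = 5.57e-30), with an estimated correlation (adjusted p = 0.0245) and by fry (adjusted p = 0.000503). The mean log2 level of the 48 genes was 8.08 ± 0.0233 in the empty vector arrays and 7.63 ± 0.0295 in the arrays labelled CHES1 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Without empty vector replicate 1, empty vector replicate 2 or CHES1 replicate 1, 12, 13 and 13 members were called lower.

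The decreases reached several machines of the cilium, which were divided into parts after the values were seen. In these counts a gene fell only where it was called. Called or not, 43 members of the list lay below 0 and 5 above. In intraflagellar transport complex B, which carries cargo toward the ciliary tip, 4 of 10 measured genes fell, among them IFT57 by 1.18 (SE 0.0719, limma adjusted p = 0.000696) and IFT74 by 0.87. In complex A, which works in the return transport, 3 of 6 fell, led by WDR19 with a decrease by 0.94 (SE 0.0585, limma adjusted p = 0.000711). Of 10 genes of the BBSome, a coat complex for ciliary membrane proteins, and its assembly, 5 fell, including ARL6 by 0.95 and BBS1 by 0.88. Of 11 genes of the transition zone, the gate at the ciliary base, 6 fell, including RPGRIP1L by 0.84, TCTN1 by 0.80 and TMEM67 by 0.71. The anterograde kinesin subunits KIF3A and KIF3B fell by 0.58 and 0.59, and KIF7 was not called. Of 5 hedgehog pathway genes, TULP3 fell by 0.45, whereas GLI1 differed by 0.17 (limma adjusted p = 0.405) and PTCH1 by -0.19 (limma adjusted p = 0.268). FOXJ1, a forkhead regulator of motile cilia, differed by 0.06 (limma adjusted p = 0.771). The other members that were not called included IFT88 at -0.75 (limma adjusted p = 0.0565), B9D2 at -0.67, TTC8 at -0.38 and BBS9 at -0.32. They also included IFT80 at -0.07, IFT20 at 0.01 and OFD1 at -0.0043.

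**Figure D3:**
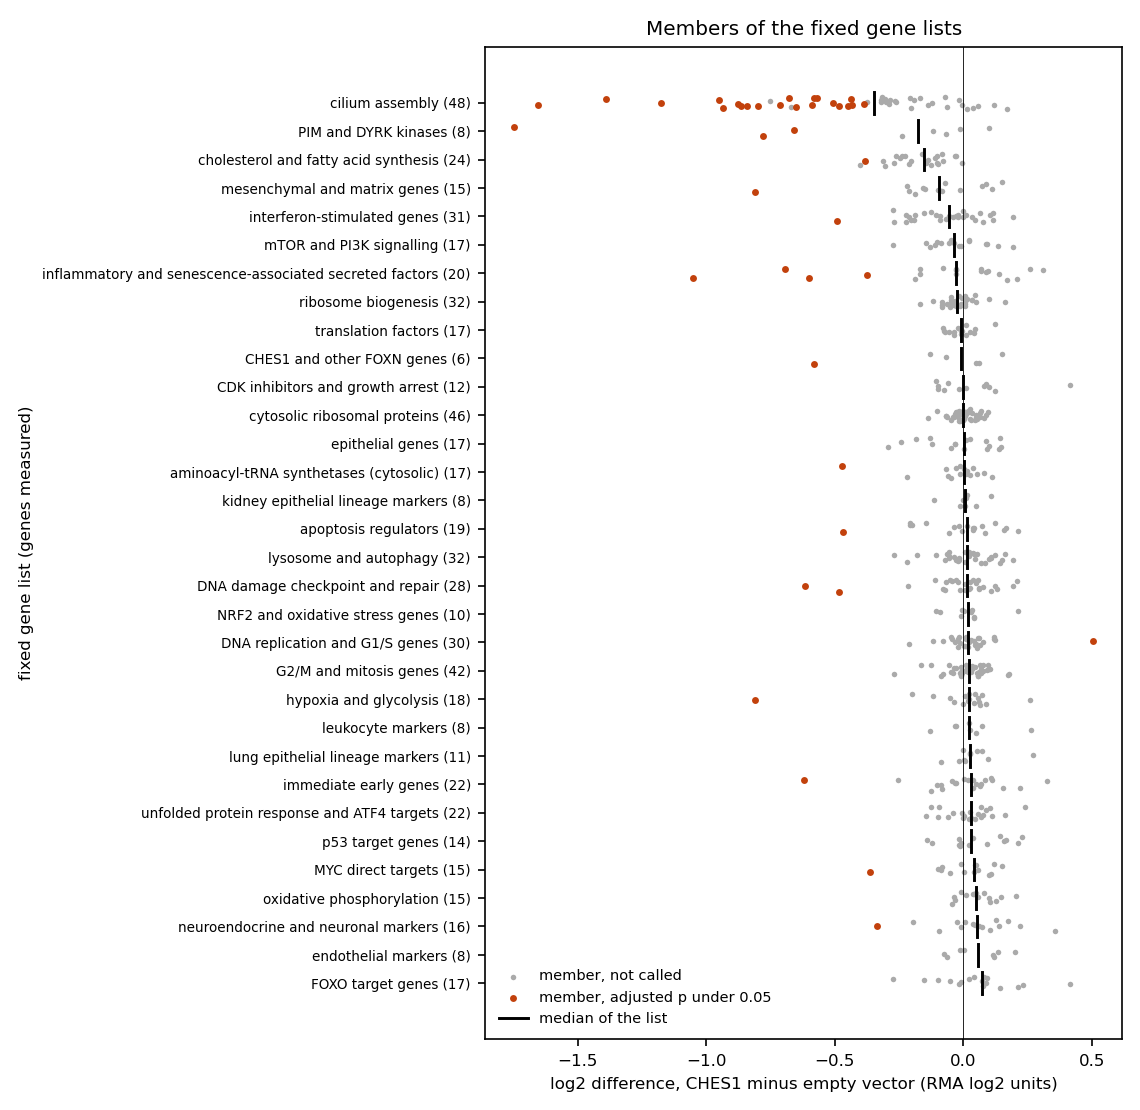
Log2 difference (arrays labelled CHES1 minus empty vector, n = 3 each) of every measured member of the 32 tested gene lists, in order of the list median (black bar), with called members in orange. The cilium assembly list lies lowest, with a median of -0.35 and 21 of 48 members called, and the median of the 46 ribosomal protein genes lies at -0.00018.

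Genes of cholesterol and fatty acid synthesis were all slightly lower, with 1 of 24 called. MSMO1, a sterol oxidase of the cholesterol pathway, fell by 0.38 (SE 0.0713, limma adjusted p = 0.0496). Adjusted over the list alone, 6 were lower and 0 higher. All 24 differences lay below 0, with a median of -0.15. Examples chosen after their values were seen are FASN, the fatty acid synthase, at -0.31 (limma adjusted p = 0.175), and HMGCS1, which makes the precursor of mevalonate, at -0.23 (limma adjusted p = 0.204). The list was called by camera (adjusted p = 1.25e-07) and fry (adjusted p = 0.0207), but had an adjusted p = 0.441 with an estimated correlation. With the preset correlation, camera also called up to 4 lists when the 6 arrays were divided in the 9 other ways, and this list in 4 of the 9. Each of those splits exchanges 1 array of each group, so it keeps part of the labelled difference and does not show what chance gives. The cilium and cholesterol lists and the PIM and DYRK kinases were the 3 called among 32 tested, all lower. With an estimated correlation the cilium list alone was called. fry called the same 3 for a shift in 1 direction and 19 lists for change in either direction.

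The 12 genes that rose did so by less than the leading decreases. The largest difference was in KRTAP9-1, a keratin-associated protein gene, at 0.85 (SE 0.0928, limma adjusted p = 0.00614), from a low level of 4.74 ± 0.157 to 5.59 ± 0.0896. TOP1P2, a pseudogene of topoisomerase 1, rose by 0.62 at a level of 3.97 in the controls, which is under the lower quartile of all probe sets (4.72 to 4.76 per array). CCNE1, the cyclin that drives entry into S phase, rose by 0.50 (SE 0.0597, limma adjusted p = 0.00771), from 9.60 ± 0.0224 to 10.10 ± 0.0585. The ribonuclease gene RNASET2 rose by 0.49, CA2 by 0.48 (limma adjusted p = 0.00689), the adipogenic nuclear receptor gene PPARG by 0.44 and MOCOS, a molybdenum cofactor sulfurase, by 0.41. STC1, which encodes the secreted hormone stanniocalcin, rose by 0.37, the lysosomal protease gene CTSV by 0.35 and the transcription factor gene ETS2 by 0.29. The 2 remaining genes, MIR941-1 at 0.38 and LINC00552 at 0.34, fell outside the rule and were chosen after their values were seen.

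Genes of protein synthesis that had a named probe set were not called as groups. Of 79 listed cytosolic ribosomal protein genes, 46 were measured. Of these, 0 were called by limma and 0 had an unadjusted p under 0.05 (median -0.00018, camera adjusted p = 0.83, fry adjusted p = 0.947). The same held for the 17 measured of 48 listed translation factors, with 0 called and 0 at an unadjusted p under 0.05 (median -0.0094, camera adjusted p = 0.942). The listed genes of the EIF2, EIF3, EIF4A and EIF4G families were not among those measured. Of 52 listed ribosome biogenesis genes, 32 were measured, with 0 called and 1 lower at an unadjusted p under 0.05 (median -0.02, camera adjusted p = 0.804). Among 17 cytosolic aminoacyl-tRNA synthetases, WARS1, which charges tryptophan tRNA, was the called member and fell by 0.47 (SE 0.0643, limma adjusted p = 0.0139), with 1 lower adjusted over the list alone (median 0.0019, camera adjusted p = 0.83). Of 15 MYC targets, ODC1, the rate-limiting enzyme of polyamine synthesis, fell by 0.36 (limma adjusted p = 0.0348), and MYC itself differed by 0.05 (limma adjusted p = 0.852; list median 0.04, camera adjusted p = 0.867, with 1 lower adjusted over the list alone). Of 34 listed mTOR and PI3K signalling genes, 17 were measured, with 0 called and 1 lower at an unadjusted p under 0.05 (median -0.04, camera adjusted p = 0.83). In the ribosomal protein, translation factor, ribosome biogenesis and mTOR lists, 0 genes were called adjusted over the list alone.

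Cell division genes were not called as groups either. Of 42 genes of G2/M and mitosis, 0 were called by limma and 1 was lower at an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.501, fry adjusted p = 0.884). Of 30 genes of DNA replication and G1/S, CCNE1 rose and 0 fell, also adjusted over the list alone (median 0.02, camera adjusted p = 0.421). Of 25 listed CDK inhibitors and growth arrest genes, 12 were measured, and CDKN2A was the only CDK inhibitor among them. Of these 12, 0 were called over all genes and 1 was higher adjusted over the list alone (median -0.0031, camera adjusted p = 0.85). Most CDK inhibitors, CDKN1A and CDKN1B among them, had no named probe set and were not tested. Among 28 genes of DNA damage checkpoints and repair, 2 fell, also adjusted over the list alone. TP53BP1, which binds chromatin at DNA breaks, fell by 0.62 (SE 0.0582, limma adjusted p = 0.00404), and XRCC1, a scaffold of single-strand break repair, fell by 0.48 (SE 0.0566, limma adjusted p = 0.00739). That list was not called (median 0.02, camera adjusted p = 0.956). Of 27 listed p53 target genes, 14 were measured, without CDKN1A and MDM2. Of these 14, 0 were called and 1 was higher at an unadjusted p under 0.05 (median 0.03, camera adjusted p = 0.396). Adjusted over the list alone, 0 were called among the p53 targets and among the genes of G2/M and mitosis. Among 19 apoptosis regulators the BCL2 family member BAD fell by 0.47 (limma adjusted p = 0.0353), with 1 lower adjusted over the list alone (median 0.01, camera adjusted p = 0.942).

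Secreted and matrix genes included several decreases, while their lists were not called. Of 20 inflammatory and senescence-associated secreted factors, 4 fell and 0 rose, with 4 lower and 1 higher adjusted over the list alone (median -0.03, camera adjusted p = 0.521). The share called lower was 20%, beside 1.37% of genes outside the cilium list, and this difference was not tested. The list was among the 19 that fry called for change in either direction (adjusted p = 4.32e-05). The collagenase MMP1 fell by 1.05 (SE 0.118, limma adjusted p = 0.00682), from 7.12 ± 0.109 to 6.07 ± 0.228. The chemokine CCL2 fell by 0.69 (SE 0.127, limma adjusted p = 0.0461), and IGFBP3 and ICAM1, outside the naming rule and chosen after their values were seen, fell by 0.60 and 0.37. Of 15 mesenchymal and matrix genes, LOX, which crosslinks collagen, fell by 0.81 (SE 0.0934, limma adjusted p = 0.00729), and 0 rose, also adjusted over the list alone (median -0.10, camera adjusted p = 0.147). Of these 15, 11 lay below 0 and 6 were lower at an unadjusted p under 0.05, and with the trend and robust prior this list was among the 5 called. LOX was also the called member of 18 hypoxia and glycolysis genes, with 1 lower and 1 higher adjusted over the list alone (median 0.02, camera adjusted p = 0.867). Of 22 immediate early genes, DUSP6, a phosphatase that dampens ERK signalling, fell by 0.62 (SE 0.0778, limma adjusted p = 0.0102), with 1 lower and 1 higher adjusted over the list alone (median 0.03, camera adjusted p = 0.83). Of 31 interferon-stimulated genes, SAMD9 fell by 0.49 (limma adjusted p = 0.0303), with 1 lower adjusted over the list alone (median -0.06, camera adjusted p = 0.258).

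Of 17 epithelial genes 0 were called and 3 were lower at an unadjusted p under 0.05 (median 0.0018, camera adjusted p = 0.942), and 0 were called adjusted over the list alone. For 15 oxidative phosphorylation genes (median 0.05, camera adjusted p = 0.155), 10 NRF2 and oxidative stress genes (median 0.02, camera adjusted p = 0.83), 22 unfolded protein response and ATF4 targets (median 0.03, camera adjusted p = 0.521), 32 lysosome and autophagy genes (median 0.01, camera adjusted p = 0.804) and 17 FOXO targets (median 0.07, camera adjusted p = 0.421), limma called 0 genes over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05, these lists held 1, 1, 2, 2 and 2 higher and 0, 0, 1, 2 and 2 lower genes. Of 62 listed oxidative phosphorylation genes 15 were measured, and the list was called with the trend and robust prior and without CHES1 replicate 3. The median, mean and camera direction differed in sign in the lists of ribosomal proteins, aminoacyl-tRNA synthetases, MYC targets, growth arrest, DNA damage, apoptosis, hypoxia, immediate early and epithelial genes, all with a median within 0.05 of 0. None of the 25 replication-dependent histone genes was measured by a named probe set, and that list was not tested.

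The lists of markers of other cell types were not called. Of 8 leukocyte markers (median 0.02, camera adjusted p = 0.804), 8 endothelial markers (median 0.06, camera adjusted p = 0.421) and 8 kidney epithelial markers (median 0.0076, camera adjusted p = 0.902), limma called 0 over all genes and 0 adjusted over the list alone, and at an unadjusted p under 0.05 there were 1, 1 and 0 higher and 0 lower. Of 11 lung epithelial markers 0 were called over all genes and 1 was higher adjusted over the list alone (median 0.03, camera adjusted p = 0.421). Of 16 neuroendocrine and neuronal markers, the synaptic vesicle protein gene SYT1 fell by 0.33 (limma adjusted p = 0.0497), with 1 lower and 1 higher adjusted over the list alone (median 0.05, camera adjusted p = 0.421).

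Of the 37 named genes that were called, 21 stayed called without any single array, and 16 were lost without at least 1 array. Of these, 8 were lost whichever array was left out, namely BAD, MSMO1, ODC1, SYT1, ETS2, CTSV, STC1 and MOCOS. The 16 were PIM2, DYRK1B, DUSP6, WARS1, CCL2, SAMD9, BAD, MSMO1, ODC1, SYT1, RNASET2, PPARG, MOCOS, STC1, CTSV and ETS2, whose highest adjusted p over the alternatives ran from 0.0503 for DUSP6 to 0.206 for SYT1.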

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

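Some tests in this part were chosen only after the result was seen: whether FOXN3 probes lie outside the vector, and whether the cilium list holds the excess of decreases.

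Probe sets without a gene name, which the report's comparison leaves out, also carried signal. When all 53617 probe sets were tested together, limma called 44, all lower in the arrays labelled CHES1, and 16 of these were among the 37519 unnamed probe sets. The other 28 were among the 16098 named probe sets, so calls were rarer among the unnamed ones. At an unadjusted p under 0.05, 1442 unnamed probe sets were lower and 1596 higher. Over all probe sets the lean was the other way, with 2368 lower and 2058 higher. The lower unnamed ones included probe set 16828485 at -1.53 (SE 0.109, adjusted p = 0.0126) and probe set 16937766 at -1.41 (SE 0.084, adjusted p = 0.00946). The largest unnamed increase, 2.06 in probe set 17068610, was not called (adjusted p = 0.0663) and lay at a mean level of 3.55. No explanation was tested for these.

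The first pattern is the decrease of cilium assembly genes, with a median of -0.35 over 48 genes. Signal level was argued against, because the median lay at percentile 0 of 10000 random lists matched on mean signal, whose medians ran from -0.09 to 0.06. For a change in the share of dividing cells, the mean of 72 cell division genes was taken per array. It was 10.39 ± 0.0347 (SD) in the empty vector arrays and 10.41 ± 0.00632 in the arrays labelled CHES1. The difference was 0.0202 (exact permutation p = 0.4), so these genes gave no sign of such a change. As a covariate this mean could hardly move the cilium median, because it barely differed between the groups, and no conclusion is drawn from that fit. With it the median was -0.36 (95% bootstrap interval -0.52 to -0.28), and 864 other genes moved by over 0.1. It left 116 genes and 14 cilium genes called, against 236 and 21 without it, a drop whose cause was not tested. A direct or indirect effect of the introduced CHES1 may underlie the pattern and stays open as a hypothesis, found and tested on the same arrays, with hybridization batch untested.

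The second pattern is the absence of a FOXN3 increase. An exchange of 1 array between the groups was argued against, since the 9 other splits of the 6 arrays, each of which makes such an exchange, called at most 0 genes against 236, with 426 to 805 genes at an unadjusted p under 0.05 against 1763. Probes outside the part that the vector carries could give a flat FOXN3, as could little expression from the vector, and these cannot be told apart from an upper bound of 0.12, because the position of the probes is not given in the sources used here. A relabelling of all 6 arrays would leave the number of called genes as it is and turn every direction, and no test here excludes it.

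The third pattern is the excess of decreases among called genes. Of the 215 called genes outside the cilium list, 203 (94.4%) were lower. With 48 measured genes against 224 lower calls, the list was too short to hold the excess. That outcome was fixed by the counts. Genes with known roles in cilia are also among the 203, so the part of cilium genes as a class in the excess was not tested. The normalization between arrays stays open as a cause. The share of lower genes was at least 94.2% under median centring, repeated quantile normalization and cyclic loess, but the deposited values were already normalized, and these settings moved 0 genes by over 0.1 and none by more than 0.0406. No biological explanation was tested beyond the group itself.

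With 6 arrays there are 10 splits into groups of 3, too few for a share under 0.05. The 9 other splits each exchange 1 array of each group. They keep part of the labelled difference and add the rest to the spread within groups, so their calls do not show what chance alone gives. For genes called changed by limma 1 of the 10 splits reached the real count of 236, with 0 as the highest other. For higher genes 1 split reached 12 and for lower genes 1 split reached 224, each with 0 as the highest other. For gene lists called by camera with the preset correlation, 3 of the 10 splits reached the real count of 3, with 4 as the highest other. The cilium list was called in 7 of the 9 other splits, with a lowest adjusted p of 0.000312 against 5.57e-30 and a median of at most 0.16 in size against 0.35. The PIM and DYRK kinases were called in 0 of them. With an estimated correlation the other splits called 0 lists.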

How the results depend on the processing

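The tests of protein-coding genes only and the counts of cilium genes were added after the data were seen. With the replicate number as a block, 147 genes were called and 137 were lower, with 134 of the 147 among the 236; the deviations of same-numbered arrays correlated at -0.0158, 0.0926 and -0.0258, and 1 of 3 arrays in each group lay closest to its own number. With the block 27 of the 37 called named genes stayed called, and SAMD9, BAD, MSMO1, ODC1, SYT1, ETS2, CTSV, STC1, MOCOS and PPARG did not. Median centring ended the calls of ETS2, CTSV and MOCOS, repeated quantile normalization those of CCL2, BAD and SYT1, and cyclic loess that of MSMO1. The trend and robust prior called 372 genes (26 higher, 346 lower) and 5 lists, adding oxidative phosphorylation and mesenchymal genes. Array quality weights called 36 higher genes. A mean log2 of at least 5 gave 23 higher genes, one of at least 6 gave 385 genes (36 higher, 349 lower), and protein-coding genes only gave 23 higher. An adjusted p under 0.01 left 86 genes (4 higher, 82 lower) and one under 0.1 gave 358 with 39 higher. Over all probe sets limma called 44, all lower and 0 higher (2058 higher and 2368 lower at an unadjusted p under 0.05), where more features were tested. Against a fold of 1.2, 49 passed (1 higher, 48 lower). Camera with an estimated correlation called 1 list, and rank-based camera called 2, without the PIM and DYRK kinases. Leaving out 1 array at a time gave 96 to 160 genes, 4 to 9 higher, 92 to 151 lower, 12 to 17 cilium genes and PIM2 differences of -0.88 to -0.69, with fewer arrays in each fit; the FOXN3 difference was -0.21 to -0.0047 over all settings and never called. PIM1, never called, reversed to 0.026 with array weights, 0.020 with repeated quantile normalization and 0.011 with cyclic loess, and ranged from -0.050 to 0.055 over left-out arrays. Except where stated, the cause was not tested. The 37 called named genes kept their direction in every setting that tested them. Of 650 values of the 41 named genes other than FOXN3 and PIM2, 553 kept direction and side of the threshold and 92 lost the call. A further 1, in DYRK1A, gained the call, and 4 reversed, all in PIM1. No detection values were used, so which low signals lie above background is unknown.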

Other observations

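The test of symbol families by the share of lower genes was chosen only after the result was seen, and the genes named here were chosen after their values were seen.

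Single called genes with known roles in cilia were picked by hand from outside the cilium list and were not tested as a group. CFAP206 fell by 1.27 (SE 0.0824, limma adjusted p = 0.000729) and CFAP300 by 1.23 (SE 0.133, limma adjusted p = 0.00607). MNS1, a structural protein of sperm flagella, fell by 1.06, and CEP19, a centrosomal protein of early ciliogenesis, by 1.05 (SE 0.102, limma adjusted p = 0.00427). The intraflagellar transport genes CLUAP1, IFT56 and IFT70B fell by 0.95, 0.63 and 0.57. DYNC2I1, the partner chain of DYNC2I2 in the ciliary dynein, fell by 0.60. ARMC9 and TMEM107, proteins of the ciliary base, fell by 0.87 and 0.64, and ARL3, a small GTPase that releases ciliary cargo, fell by 0.62. CCP110, which caps centrioles and holds back cilium formation, also fell, by 0.57 (SE 0.0675, limma adjusted p = 0.00777).

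A hypothesis was that other gene families moved with the cilium list. Genes outside that list were grouped by symbol stem, and 230 stems had 8 or more genes. Camera called 7, against 3 at most in the other splits of the arrays, which keep part of the labelled difference. CFAP, PCDHB, SAMD, ARMC and NEK were lower, PRAMEF and TMC were higher, and 0 were called with an estimated correlation (adjusted p = 0.991 for each). By the share of genes called lower, 1 stem stood out. In CFAP, the cilia and flagella associated proteins, 9 of 41 genes (21.95%) were lower against 1.37% of all genes outside the list (one-sided Fisher's exact test, adjusted p = 7.77e-07). The stems CEP (2 of 36, adjusted p = 1) and ARL (2 of 13, adjusted p = 0.757), which also hold centrosomal and ciliary genes, did not pass this test. Nor did RSPH (1 of 8), SPAG (1 of 12) and DRC (0 of 10), further stems with genes of cilia and flagella. The 1 stem called suggests that the decrease may extend to CFAP genes, a hypothesis to be tested on other samples.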
